A study of Mus musculus with 6 samples.

How the data were processed

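RNA of flow-sorted HSCs from 3 young and 3 old male mice was purified with a kit for very small samples, turned into libraries with a low-input kit and sequenced as single-end reads of 50 bases, per the labels' protocols and the series design. The design calls the 3 samples of each age biological replicates, and p-values of single genes measure the spread between these samples. The surface markers of the sort and the number of cells are not given in the sources used here. The submitters' processing notes name Salmon, DESeq2, FastQC, MultiQC and the genome build GRCm38, without versions, roles or order.

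The deposited table of estimated counts held whole numbers for 16312 genes in 6 columns, so no rounding was needed, and no gene had fewer than 11 counts in total. A second table held the authors' own comparison, with a base mean (a normalised signal) that the authors computed per gene, the authors' log2 fold change and its standard error, a test score per gene that the authors deposited, and the deposited p-value and adjusted p-value. The authors' log2 fold changes have the sign of young over old, as found by comparison with the counts, and 663 genes had no adjusted p. The deposited base mean lay within 2% of the mean of the counts over size factors for 77.4% of genes, so the deposited counts and the authors' comparison do not match in every gene. Each library was assigned to its group by its label, and the replicate numbers follow the order of the samples and pair nothing. The label of young replicate 2 carries a different library number in its title than in its description, and its column was matched by the title. The fit without this library gives 423 changed genes.

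Genes were matched by Ensembl identifier to the GRCm38 annotation, which gave a symbol for 16301 genes and called 16207 protein-coding, and 14500 identifiers had the version of that annotation. Coordinates are those of GRCm38, counted from 1. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's default filter (a minimum count of 10 and a minimum total of 15), which left 14288, and library sizes were scaled by TMM factors between 0.955 and 1.06. Changes were tested with edgeR's quasi-likelihood F test for the group term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests reported in the text were two-sided, except the permutation test of the similarity of libraries, which was one-sided. Log2 CPM used a prior count of 2.

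The design, the tests, 40 gene lists and the alternatives were fixed before the data were examined. Lists with at least 5 measured members, 39 of them, were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, and p-values were adjusted over the lists. Camera at the preset correlation sets list members against the other genes, so the size of its p-value does not measure replication across mice. The correlation was estimated at 0.0559 for immediate early genes and 0.215 for aged HSC genes, above the preset. The list of nuclear and non-coding RNAs had fewer than 5 measured members and was not tested. With an estimated correlation 3 lists passed, those of aged HSC genes, immediate early genes, and monocytes and macrophages. The lists of p53 targets, glycolysis and NF-kB genes lost their calls although their estimates (−0.00543, 0.00158 and 0.00867) lay below the preset. A call lost in this setting thus need not reflect correlation within the list. Of the listed genes 70 stood in 2 or more lists. Class shares were compared with exact permutation tests over 20 arrangements, which cannot give a p under 0.1, and 1 class, the share of Lars2 and Gm20594, was added after the data were seen. That class took 1.06% ± 0.0829 of counts in young and 1.75% ± 0.519 in old mice (SD, n = 3, exact permutation p = 0.1). Haemoglobin genes took 0.00219% and 0.00125% (exact permutation p = 0.3), immunoglobulin genes 0.000512% and 0.000989% (exact permutation p = 0.2) and the top 100 genes 19.3% and 20.8% (exact permutation p = 0.2).

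Genes named in the text follow a rule set in advance. They are the 12 genes with the largest fold change in each direction among those called, at 10 CPM or more in the higher group and without overlap of the groups, leaving out predicted genes and pseudogenes, then the 4 members of each list with the smallest p, and every called member of the aged HSC list and the substrain and sex list. The rule gave 188 genes, and exceptions are said to be picked after their values were seen. A fold against a group without counts is a lower bound against a floor of 3 counts over the group. No list median moved when such genes were set at that bound.

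Pairs of libraries differed by 22.8 to 85.2 in chi-square per degree of freedom over genes, and no pair looked like a library deposited again. The fit was tested on simulated counts for the same 14288 genes with 200 of them changed. It called 8.96% of genes changed by a log2 fold of 0.58 with the right sign, 47.8% at 1 and 72.7% at 2, and 3.37% of its calls were unchanged genes. With no gene changed it made 1 call, and camera called the shifted list and 0 of 40 unshifted ones. The simulated genes were drawn independently, whereas the estimated correlation within the G2 and mitosis list was 0.474. The simulation thus does not show how often camera calls unshifted lists of correlated genes.

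Alternatives were DESeq2 size factors, upper quartile factors or library size alone, no filter or stricter filters (at least 1 CPM in at least 3 libraries, or a mean of at least 10 CPM), the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, a robust fit, the edgeR exact test, a test against a fold of 1.5 and other thresholds. Each library was left out in turn, 4 gene classes were left out, and a trend against GC content and gene length, known for 99.93% of tested genes, was removed. Counts thinned to the lowest library total were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.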

Results

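Haematopoietic stem cells (HSCs) were isolated by flow cytometry from the bone marrow of male mice of 2 age groups, and their RNA was sequenced. The young group held 3 mice aged 8 to 12 weeks and the old group 3 mice aged 22 months. Both groups were labelled as B6 controls of a study of parabiosis, the surgical joining of animals. The count table held 16312 genes, and the total count per library ran from 12494557 in old replicate 2 to 30931680 in young replicate 3. Between 15235 and 15981 genes had at least 1 count in a library, and 14288 genes passed the filter on low counts and were tested. Fold changes are given as old over young, with standard errors (SE), and levels as CPM, which are counts relative to the TMM-scaled size of the library.

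The comparison asks how the transcripts of HSCs differ between old and young mice. HSCs of old mice held more transcripts of immediate early genes, which cells switch on within minutes of a stimulus, such as Jun (7.76-fold), Egr1 (9.92-fold) and Fos (18.2-fold). They also held more of the genes listed before as markers of aged HSCs, among them Selp (8.91-fold) and Vwf (5.37-fold), and of some HSC surface markers such as Procr and Slamf1. Genes of DNA replication (22 of 42) and mitosis (27 of 44) were lower in old mice, for example Mki67 and Top2a, although both list calls were lost with an estimated correlation (adjusted p = 0.0925 and 0.0935). Also lower were the lymphoid and multipotent progenitor genes Flt3, Satb1 and Cd34. Markers of macrophages were also lower in the libraries of old mice, as were 6 of 23 erythroid and 3 of 8 neutrophil markers. The neutrophil list was not called, and the erythroid call was lost with an estimated correlation (adjusted p = 0.216) and with fry (adjusted p = 0.0866).

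In all, 570 genes passed an adjusted p of 0.05 (edgeR), 350 of them higher and 220 lower in old mice, and 209 of the higher and 144 of the lower ones differed by at least 2-fold. With library size alone as the scaling, the split was 310 higher and 298 lower. The 3 young and 3 old libraries did not overlap in CPM for 569 of the 570 genes, the exception being S100a8, and for 3195 (22.4%) of all tested genes, where chance gives 10%. Leaving out 1 old library moved the count of changed genes by more than 1.5 times, to 322 without old replicate 1, 345 without old replicate 2 and 245 without old replicate 3. Leaving out a young library gave 473, 423 and 463 genes for young replicates 1, 2 and 3.

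**Figure D1:**
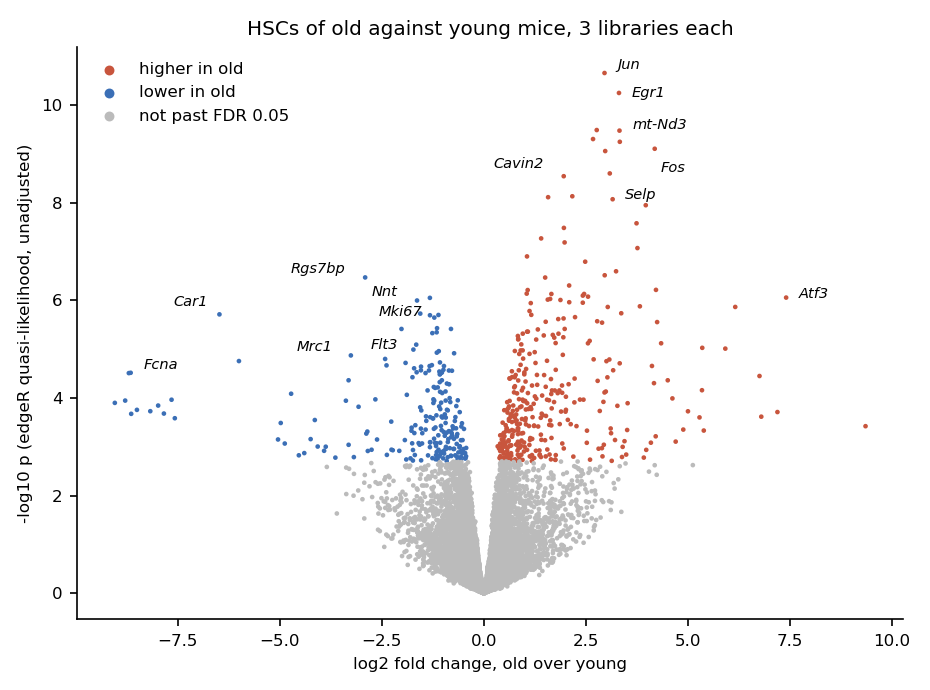
Each point is 1 of the 14288 tested genes, with its log2 fold change of old over young on the x axis and the unadjusted edgeR p on a −log10 scale on the y axis. Red points are the 350 genes higher and blue points the 220 genes lower in old mice, and genes at 0 counts in 1 group lie far out because their fitted fold changes have no measured base.

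The genes with the largest changes at 10 CPM or more were led on the higher side by Ptgs2 (log2 fold change 4.51 ± 0.71 SE), the inducible enzyme of prostaglandin synthesis, by Kcnb2 (4.34 ± 0.57), a potassium channel subunit, and by Atf3 (7.41 ± 0.79), a stress-responsive transcription factor. Ptgs2 stood at 6.12 CPM in young replicate 1 but at 0.588 and 0.611 in the other young libraries, and its log2 value ran from 4.01 to 6.46 over the alternatives. The authors' table gives Ptgs2 a log2 value of −0.51 as young over old, with an adjusted p of 0.152. Atf3 had 5 counts in the young group, and the log2 values of Atf3 and Kcnb2 ran from 6.87 to 9.06 and from 3.91 to 5.26. Kcnb2 lies on chromosome 1 from 15287254 to 15723750 and rose from 1.18 ± 0.960 to 24.5 ± 11.2 CPM (SD, n = 3). Osmr, the receptor of oncostatin M, was 13.6-fold higher, and Cldn5, a tight junction protein of endothelium, was 18.6-fold higher. The lower side was led by Car1 (log2 fold change −6.48), Ngp (−5.04) and S100a9 (−4.14), each highest in young replicate 1. With a smaller change, Rgs7bp, which binds regulators of G protein signalling, had a log2 value of −2.91. It lies on chromosome 13 from 104945904 to 105054930 and fell from 24.2 ± 1.46 to 3.22 ± 0.612 CPM (SD, n = 3, adjusted p = 0.000195). Igf1, a growth factor, was 5.23-fold lower (adjusted p = 0.00272).

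Immediate early genes had the largest median change of all lists in the fit of all 6 libraries. Of 39 measured members, 26 rose and none fell over all genes tested, and 34 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 2.03 (camera adjusted p = 6.37e-116), and the call held with an estimated correlation (adjusted p = 0.004). Jun, a subunit of the AP-1 transcription factor on chromosome 4 from 95049034 to 95052222, rose from 118 ± 15.3 to 913 ± 47.7 CPM (SD, n = 3, adjusted p = 3.12e-07). Egr1, a zinc finger transcription factor on chromosome 18 from 34859823 to 34864984, rose from 101 ± 10.8 to 999 ± 174 CPM (adjusted p = 4e-07). Fos, the other AP-1 subunit, lies on chromosome 12 from 85473890 to 85477273 and rose from 38 ± 14.8 to 690 ± 65 CPM (adjusted p = 1.55e-06). The phosphatase gene Dusp1 was 6.39-fold and Socs3, an inhibitor of cytokine signalling, 15.6-fold higher. Hspa1a and Hspa1b, the heat shock members of the list, had log2 values of −1.61 and −1.33 and did not pass, and both were picked after their values were seen. The old libraries carried consecutive numbers in the labels and the young ones did not, so any step that followed those numbers ran alongside age.

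**Figure D2:**
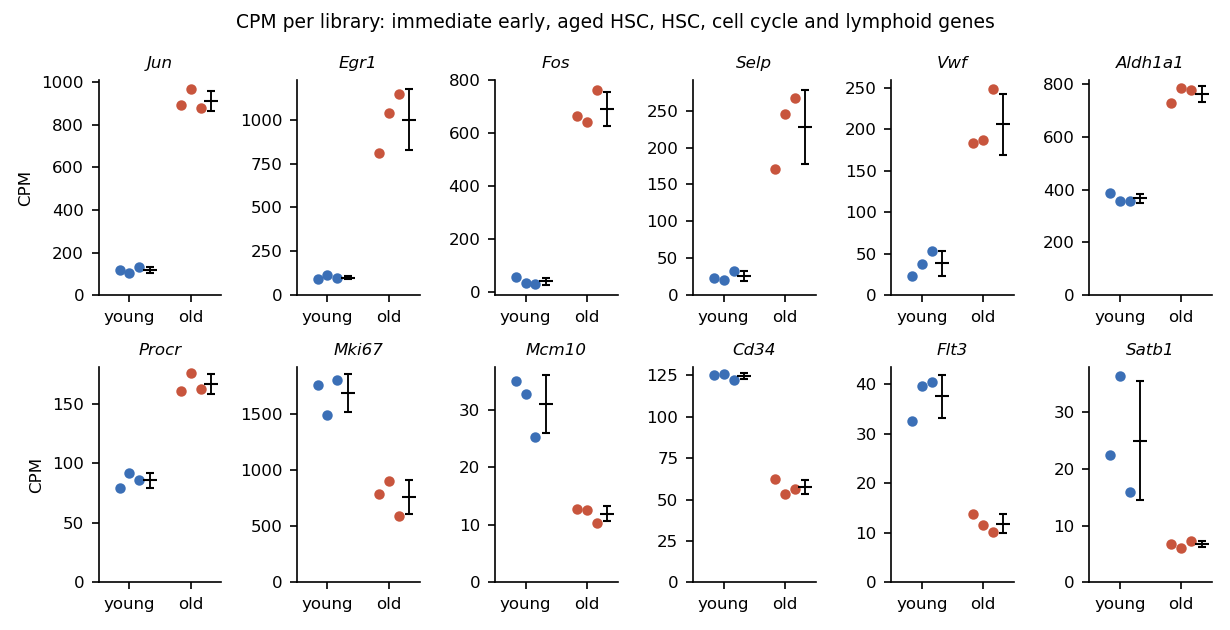
CPM of 12 genes in each of the 3 young (blue) and 3 old (red) libraries, 1 point per library, with the group mean and SD as bars beside the points. Immediate early genes, aged HSC genes and Procr are higher in every old library, and Mki67, Mcm10, Cd34, Flt3 and Satb1 are lower.

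The aged HSC list, fixed from general knowledge of ageing HSCs, had 40 measured members, of which 37 rose and none fell, and 40 rose when adjusted over the list alone. Its median log2 fold change was 1.79 (camera adjusted p = 2.25e-117), and the call held with an estimated correlation (adjusted p = 0.0164). Selp, the adhesion receptor P-selectin on chromosome 1 from 164115264 to 164150026, rose from 25.5 ± 6.73 to 228 ± 50.4 CPM (SD, n = 3, adjusted p = 9.3e-06). Vwf, the platelet adhesion protein von Willebrand factor on chromosome 6 from 125546774 to 125686679, rose from 38.3 ± 15.2 to 206 ± 36.5 CPM (adjusted p = 0.000357). The retinaldehyde dehydrogenase gene Aldh1a1 was 2.08-fold and the clusterin gene Clu 5.87-fold higher. Among 30 megakaryocyte and platelet genes, 7 rose and none fell, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.84e-08). The 2 lists share 7 genes, with Selp, Vwf, Clu and Cavin2 among the shared ones, and the megakaryocyte call was lost with an estimated correlation (adjusted p = 0.0912) and when members shared with any other list were left out (adjusted p = 0.671).

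HSC identity genes were shifted upward by less. Of 46 measured members, 9 rose and none fell, and 24 rose when adjusted over the list alone, with a median log2 fold change of 0.30 (camera adjusted p = 4.38e-13, and adjusted p = 0.119 with an estimated correlation). Without old replicate 3, 5 members rose. Procr, which encodes the HSC surface marker EPCR, rose by 0.95 ± 0.12 SE, and Slamf1, which encodes CD150, rose by 1.47 ± 0.19 on the log2 scale. Mycn rose by 0.74.

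Cell cycle genes were lower in old mice. Of 44 G2 and mitosis genes, 27 fell and none rose, and 37 fell when adjusted over the list alone, with a median log2 fold change of −0.92 (camera adjusted p = 6.04e-44, and adjusted p = 0.0935 with an estimated correlation). Mki67, the proliferation marker Ki-67 on chromosome 7 from 135689784 to 135716361, stood at 1681 ± 170 CPM in young and 759 ± 154 CPM in old mice (SD, n = 3, adjusted p = 0.00086). Ect2, needed for cell division, was 2.95-fold and the topoisomerase gene Top2a 2.15-fold lower. Of 42 S phase genes, 22 fell and none rose, and 33 fell when adjusted over the list alone, with a median of −0.67 (camera adjusted p = 6.79e-26, and adjusted p = 0.0925 with an estimated correlation). The replication factor Mcm10 fell by 1.38 ± 0.23 SE, and the flap endonuclease gene Fen1 fell by 1.23 ± 0.20 on the log2 scale. Without old replicate 1 or old replicate 3, 16 G2 and mitosis genes fell. S phase calls numbered 14 without young replicate 1, 12 without young replicate 3 or old replicate 1, 10 without old replicate 2 and 4 without old replicate 3.

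Of 61 replication-dependent histone genes, 15 fell and none rose, and 30 fell when adjusted over the list alone, with a median log2 fold change of −0.91 (camera adjusted p = 3.83e-16, and adjusted p = 0.0925 with an estimated correlation). Hist1h2bf was 5.35-fold and Hist1h1b 3.13-fold lower, although histone genes are near-identical copies and the counts of single members are uncertain. The count was 9 without young replicate 2, 7 without old replicate 1 and 8 without old replicate 3. Among 56 DNA repair genes 4 fell, with Brca1, Brca2 and Blm among them, and 11 fell when adjusted over the list alone (camera adjusted p = 4.92e-06, and adjusted p = 0.212 with an estimated correlation). None of the 4 was called without young replicate 3, old replicate 2 or old replicate 3, and the list held 1 call without young replicate 1 or old replicate 1. Of 29 cell cycle inhibitor and quiescence genes, 8 rose and 1 fell, and 14 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.82e-14, and adjusted p = 0.0912 with an estimated correlation). This list shares 5 genes with the immediate early list, with Egr1 and Nr4a1 among them, and its call was lost when members shared with any other list were left out (adjusted p = 0.11). Its 1 lower gene was called in none of the 6 fits with 1 library left out. The antiproliferative genes Btg1 and Btg2 were 2.22-fold and 10.3-fold higher. The log2 value of Btg2, 3.37, moved to 3.99 without young replicate 1.

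**Figure D3:**
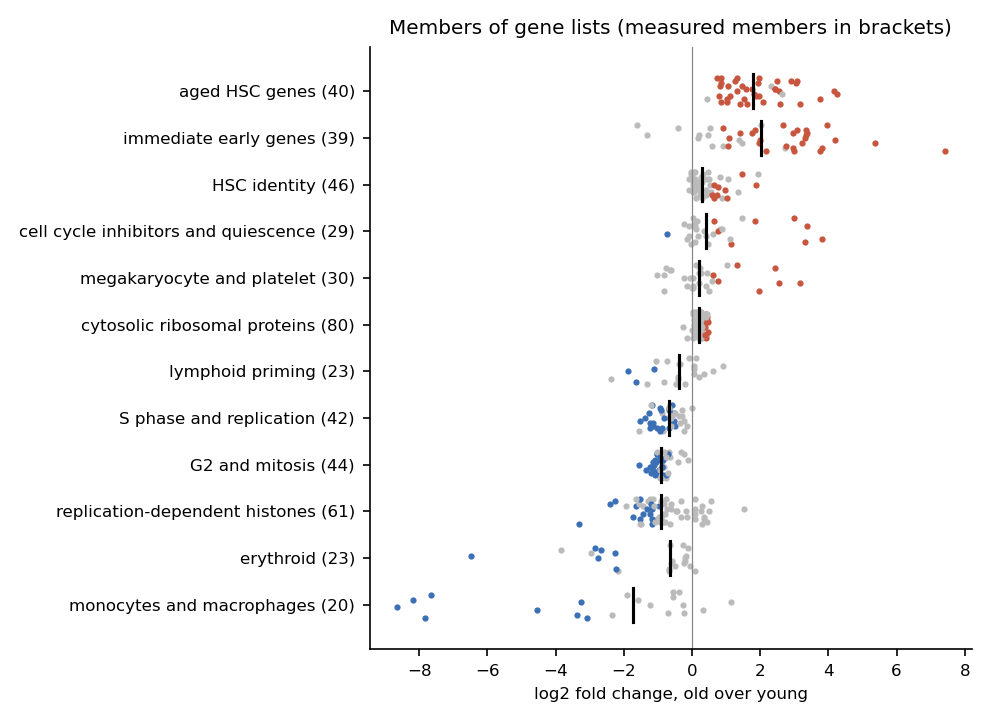
Log2 fold changes of old over young for the measured members of 12 gene lists, with red for genes called higher, blue for genes called lower and grey for genes that did not pass an adjusted p of 0.05. Black bars mark the list medians, from 2.03 for immediate early genes to −1.74 for monocyte and macrophage markers.

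Lymphoid genes were lower in old mice, with 3 of 23 members fallen and none risen, and 5 fallen when adjusted over the list alone (camera adjusted p = 0.000156, and adjusted p = 0.0925 with an estimated correlation). Cd34, a surface protein that HSCs gain as they become multipotent progenitors, lies on chromosome 1 from 194938819 to 194961279 and fell from 125 ± 1.75 to 57.5 ± 4.31 CPM (SD, n = 3, adjusted p = 0.000555). The cytokine receptor gene Flt3 fell by 1.66 ± 0.22 SE, and Satb1, a chromatin organiser of lymphoid cells, fell by 1.89 ± 0.32 on the log2 scale. Ikzf1, the lymphoid transcription factor Ikaros, had a log2 value of −0.39 and did not pass (adjusted p = 0.0512). Of 21 myeloid progenitor genes, 2 rose and 3 fell, and 3 rose and 4 fell when adjusted over the list alone, with no shift of the list (camera adjusted p = 0.467). Among them the proteinase gene Prtn3 was 3.15-fold higher, whereas the myeloperoxidase gene Mpo was 9.10-fold lower (adjusted p = 0.0442). Most of this came from young replicate 1, with 40.4 CPM of Mpo against 6.43 and 3.33 in the other young libraries, and without it the log2 fold change of −3.19 shrank to −1.42. Mpo lost its call in 7 of 19 alternatives, namely without a filter, with limma-voom with and without quality weights, without young replicate 1 and without any 1 old library (highest adjusted p = 0.316). The list held 1 higher and 1 lower call without young replicate 1 or any 1 old library, and 1 higher and 2 lower without young replicate 2.

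Markers of monocytes and macrophages had the lowest list median in the fit of all 6 libraries. Of 20 measured members, 8 fell and none rose, and 11 fell when adjusted over the list alone, with a median log2 fold change of −1.74 (camera adjusted p = 9.67e-10), and the call held with an estimated correlation (adjusted p = 0.0294). Mrc1, the mannose receptor CD206 on chromosome 2 from 14229392 to 14332057, fell from 14.9 ± 5.00 to 1.60 ± 0.807 CPM (SD, n = 3, adjusted p = 0.00194). Vcam1 was 10.4-fold lower, a log2 value of −3.38 that moved to −4.27 without old replicate 1. Fcna and Cd5l, secreted proteins of tissue macrophages, had no count in any old library and were at least 42.3-fold and at least 21.1-fold lower, against a floor of 3 counts over the old group. A count of 0 allowed up to 0.127, 0.252 and 0.137 CPM in the 3 old libraries, and floors cover counting error only. Without old replicate 1 the count was 5, and without old replicate 3 it was 3. The lower lymphoid and cell cycle genes and the higher aged HSC genes were thus measured in libraries that also differed in macrophage transcripts.

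Erythroid genes were lower in old mice for 6 of 23 members, with none higher, and for 8 when adjusted over the list alone (camera adjusted p = 1.93e-07), and the call was lost with an estimated correlation (adjusted p = 0.216) and with fry (adjusted p = 0.0866). Car1, an erythroid carbonic anhydrase, stood at 68.9 ± 68.5 CPM in young and 0.762 ± 0.0785 CPM in old mice (SD, n = 3, adjusted p = 0.000555, and 0.0938 with limma-voom). Car1 stood at 147 CPM in young replicate 1 against 41.6 and 18.2 in the other young libraries, and without it the log2 fold change of −6.48 shrank to −5.28. Young replicate 1 had the highest erythroid level, a mean log2 CPM of 4.49 over the list against 3.49 and 3.47 in the other young libraries. Without it, and likewise without any 1 of the old libraries, 2 erythroid genes fell. Of 8 measured neutrophil markers, S100a9, Ngp and S100a8 fell, and adjusted over the list alone 3 fell and 1 rose, with a median log2 fold change of −1.32 and no call for the list (camera adjusted p = 0.127). Without young replicate 1, 1 neutrophil marker fell, and without young replicate 2, 6 fell and the list passed (camera adjusted p = 9.16e-09). Without old replicate 1 no neutrophil marker fell, and without old replicate 2 or 3 the count was 1, while the list passed in all of these (camera adjusted p = 0.024, 0.00875 and 0.00243). In these 4 fits, in which 11 neutrophil markers passed the filter, their median was −4.41 without young replicate 2 and −3.92, −3.82 and −4.18 without old replicates 1, 2 and 3, the largest change of any list there. The list also passed without a filter (camera adjusted p = 0.00164) and in the edgeR exact test setting (adjusted p = 0.0328).

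Of 10 measured endothelial markers, 3 rose and none fell, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 0.52 (camera adjusted p = 0.000646, and adjusted p = 0.119 with an estimated correlation). These were Cldn5, Kdr, the receptor VEGFR2 (6.85-fold), and Clec14a (2.83-fold), while the pan-endothelial gene Pecam1 and Tie1, picked after their values were seen, had log2 values of 0.15 and −0.13. The lists of the remaining cell types were not called with camera. None of 9 B cell and none of 6 plasma cell markers passed, over all genes tested or adjusted over the list alone (camera adjusted p = 0.74 and 0.467). Of 9 T and NK cell markers 1 rose, Klrb1c, which is also in the aged HSC list, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.696). The median of this list was −0.16 although camera gave an upward direction. Of 10 dendritic cell markers Clec9a rose and Flt3 fell, also when adjusted over the list alone (camera adjusted p = 0.696). Of 8 mast cell, basophil and eosinophil markers Ccr3 fell, also when adjusted over the list alone (camera adjusted p = 0.312), a list called lower with fry (adjusted p = 0.0394), and none of these markers fell without old replicate 1 or 3. Of 10 stromal markers Runx2 fell, also when adjusted over the list alone (camera adjusted p = 0.924), with no call without young replicates 2 or 3 or old replicates 1 or 3.

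**Figure D4:**
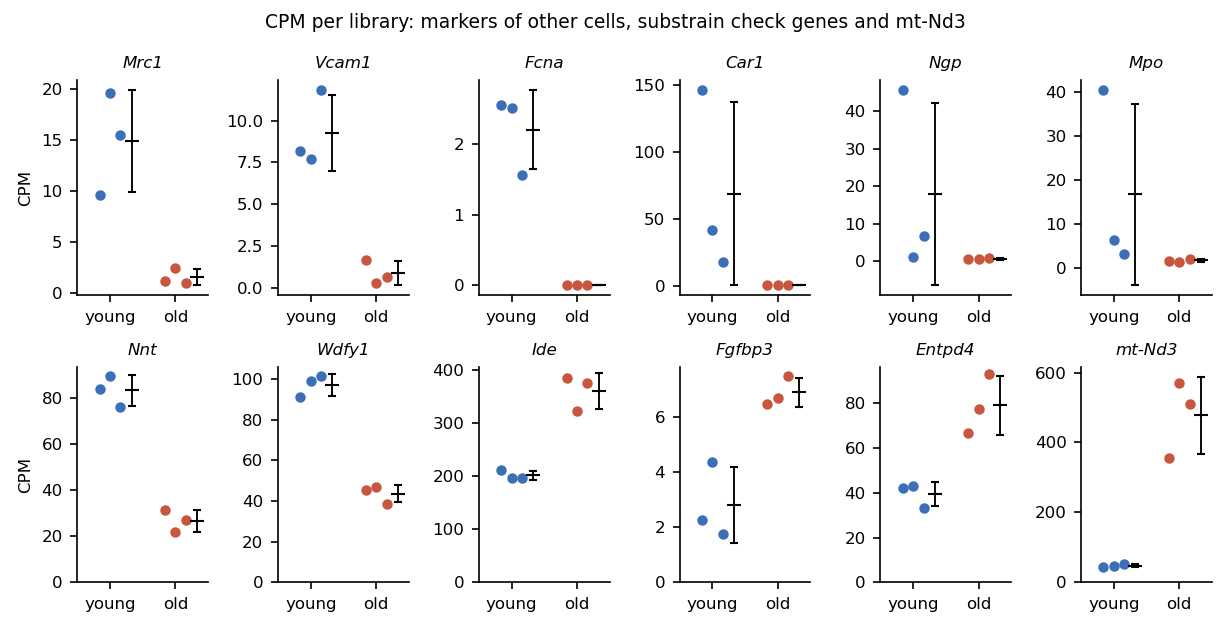
CPM in each of the 3 young (blue) and 3 old (red) libraries, 1 point per library, with the group mean and SD as bars, for markers of other cell types, substrain check genes and mt-Nd3. Mrc1 and Vcam1 are lower in all old libraries, and Car1, Ngp and Mpo are highest in young replicate 1.

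Ribosomal protein genes were slightly higher in old mice. Of 80 measured members 10 rose and none fell, and 20 rose when adjusted over the list alone, with a median log2 fold change of 0.20 (camera adjusted p = 1.24e-09, and adjusted p = 0.349 with an estimated correlation). Rps3 was 1.38-fold and Rpl3 1.36-fold higher. None rose without young replicate 2, old replicate 2 or old replicate 3, and 5 rose without young replicate 1. These genes took 7.52% ± 0.0799 of all counts in young and 8.46% ± 0.360 in old mice (SD, n = 3, two-sided exact permutation p = 0.1, adjusted 0.3 over 6 classes), and 0.1 is the smallest p that 3 against 3 allow. Mitochondrially encoded genes took 4.48% ± 0.381 and 4.74% ± 0.668 (exact permutation p = 0.6, adjusted 0.6), and 2 of the 13 rose, mt-Nd3 and mt-Nd6. Adjusted over the list alone 3 rose (camera adjusted p = 0.000322), and the call was lost with an estimated correlation (adjusted p = 0.433), with fry (adjusted p = 0.173) and with quality weights in limma-voom (adjusted p = 0.0839). mt-Nd3, a subunit of respiratory complex I on chromosome M from 9459 to 9806, rose from 47.6 ± 3.73 to 477 ± 111 CPM (SD, n = 3), while mt-Nd5 and mt-Nd4l had log2 values of 0.34 and −0.23 and did not pass. Only mt-Nd3 was called without any 1 library other than old replicate 1, and 3 were called without old replicate 1.

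Genes that check the mouse substrain and sex differed between the groups. The labels give no substrain per mouse, so a substrain difference could run alongside age for every gene tested. The series title names C57BL/6N, a substrain that carries an intact Nnt gene, whereas the C57BL/6J substrain carries a deletion in it. Nnt, the mitochondrial transhydrogenase gene on chromosome 13 from 119335448 to 119408997, fell from 83.4 ± 6.67 to 26.7 ± 4.77 CPM (SD, n = 3, adjusted p = 0.000369). Of 5 autosomal check genes 4 passed, with Wdfy1 lower by 2.23-fold and Ide and Entpd4 higher by 1.79-fold and 2.01-fold, and Fgfbp3 had a log2 value of 1.30 and did not pass (adjusted p = 0.159). Entpd4 was not called without old replicate 3 (adjusted p = 0.0552). The authors' table gives Wdfy1 a log2 value of 0.56 as young over old, with an adjusted p of 0.175. In that table Nnt, Ide and Entpd4 have an adjusted p under 0.05. The sex-linked check genes read from chromosome Y were present in all libraries, and Ddx3y was 1.47-fold higher in old mice while Eif2s3y, Uty and Kdm5d did not pass. Ddx3y was not called without young replicate 3 or without any 1 old library (highest adjusted p = 0.0942). Eif2s3y passed in 5 of 20 alternatives. These were a mean of at least 10 CPM, the DESeq2 Wald test, limma-voom with quality weights, the edgeR exact test and the fit without young replicate 3. As a list the 9 measured members had 3 higher and 2 lower calls, and 5 and 2 when adjusted over the list alone, with no shift (camera adjusted p = 0.312).

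The libraries grouped by age on average, though not in every pair. The mean Pearson correlation of log2 CPM was 0.953 within young, 0.962 within old and 0.939 between the groups. The mean within groups lay 0.0187 above that between groups (one-sided exact permutation p = 0.1, the smallest that 10 splits allow). Young replicate 3 and old replicate 1 correlated at 0.9603, above the 0.9599 of young replicates 2 and 3 and the 0.9522 of young replicates 1 and 3. Young replicate 2 was likewise closer to old replicate 1 (0.9517) than to young replicate 1 (0.9466). A first principal component with 38.1% of the variance separated the ages, and the second (22.3%) set young replicate 1 and old replicate 2 apart from the others. The SD of log2 CPM was larger in old than in young mice for 41.3% of genes, and 4 of the 10 splits gave a share as far from even. Without young replicate 1 the share was 54.4%. That fit set SDs of 3 old libraries against SDs of 2 young ones, which raises the share by itself. The 54.4% thus cannot be read as a turn of direction. The authors' deposited table gave 966 genes an adjusted p under 0.05, 559 higher in old and 407 higher in young mice. Of its 934 calls among the genes tested here, 509 were also called here, all with the same sign. Independent lists would share 37.3, but both comparisons are of the same young and old groups, so a large overlap was built in. Across genes, which are not independent replicates, the 2 sets of fold changes had a Pearson correlation of 0.800 and the same sign for 90.6%. Their sizes could differ widely. As young over old the authors' log2 value was 1.69 for Car1 and 1.75 for Knl1, while the values here as old over young were −6.48 and −1.21. How the authors estimated their fold changes is not given, so the 2 scales may not be alike.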

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

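The thinning of counts was chosen after seeing the data, and all other alternatives before. No scaling or filter moved the number of changed genes by more than 1.5 times (485 to 697 genes, 570 as reported), and thinning to the lowest library total gave 578. With limma-voom it was 564, with quality weights 675 and with a robust fit 579. The other tests and thresholds moved it by more. The DESeq2 Wald test gave 1100 genes (613 higher, 487 lower), which include 565 of the 570, and the edgeR exact test gave 1015 (568 and 447). A test against a fold of 1.5 gave 173 (123 and 50), an FDR of 0.01 gave 242 (165 and 77) and an FDR of 0.10 gave 939 (534 and 405), by their construction. Leaving out 1 library gave 245 to 473 changed, 166 to 308 higher and 79 to 167 lower genes, with fewer samples. The number of gene lists past the threshold was 3 with an estimated correlation, 16 without shared members and 16 to 22 with 1 library left out, against 21. Of 134 named genes that were called, 85 kept their call in every alternative fit in which they were tested. In 227 of 2648 values the call was lost while no direction turned. Neither these values nor those of the lists below include the test against a fold of 1.5 or the other thresholds. Of 480 values for the 21 called lists 41 lost the call, and no direction turned. Among 18 lists that were not called, 14 of 407 values passed and 15 turned direction, and the cause was not tested. Those that turned were, as adjusted p, stromal markers with library size alone (0.947), fry (0.993) and without old replicate 3 (0.901), B cell markers without a filter (0.740) and without old replicate 3 (0.845), and plasma cell markers without a filter (0.897) and without old replicate 2 (0.918). Turned or not, these 3 lists lay between 0.574 and 0.915, 0.598 and 0.866, and 0.371 and 0.918 with 1 library left out. Myeloid progenitor genes turned at a mean of at least 10 CPM (0.059), and T and NK cell markers with limma-voom (0.985), with quality weights (0.941) and without shared members (0.395). Oxidative phosphorylation genes turned without young or old replicate 1 (0.831 and 0.861) and protein folding genes without young replicate 3 or old replicate 1 (0.118 and 0.739), and over all fits with 1 library left out they lay between 0.328 and 0.861 and between 0.0545 and 0.856. The log2 fold change of Cd8b1 lay between −1.83 and 0.14 and that of Vpreb3 between −0.44 and 2.85 with 1 library left out. The share of genes with the larger SD in old mice, 41.3%, lay between 30.4% and 54.4% with 1 library left out. Those fits set SDs over unequal numbers of libraries against each other, which moves the share by itself. The correlation with the authors' fold changes, 0.800, was 0.912 at a mean of at least 10 CPM and 0.676 to 0.713 with 1 library left out. Depth limits low genes most. A count of 0 in old replicate 2, the shallowest library, allows up to 0.252 CPM.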

Other observations

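The tests of the immediate early, macrophage and substrain patterns below were chosen only after those results were seen, and the count over splits of the libraries was chosen before. The test with other cell types was also widened from 6 to 8 lists and limited to members under 10 CPM after its first version had been run. The values of that first version are not given here.

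Stress, signalling and metabolism lists moved little. Of 35 NF-kB and inflammatory genes, 3 rose, Osmr, Nfkbiz and Ptgs2, and Rel fell, over all genes tested and adjusted over the list alone (camera adjusted p = 0.0147, and adjusted p = 0.153 with an estimated correlation). This call was lost without young replicate 3 (adjusted p = 0.112), without old replicate 1 (adjusted p = 0.0928) and when members shared with any other list were left out (adjusted p = 0.121). The fall of Rel was called in the fit without young replicate 3 but in no other fit with 1 library left out. Of 31 p53 target genes, the kinase gene Plk2 (3.89-fold) and Btg2 rose and the mitotic genes Ckap2 and Gtse1 fell, and 7 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0219, adjusted p = 0.142 with an estimated correlation, 0.113 without young replicate 3, 0.0845 without shared members and 0.0799 at a mean of at least 10 CPM). Without young replicates 2 or 3 or any 1 old library, 1 p53 target fell. Of 33 antioxidant genes, the metallothionein gene Mt1 (6.03-fold) and Gpx3 (7.16-fold) rose and Hmox1 fell, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0303, adjusted p = 0.216 with an estimated correlation). This call was lost without young replicate 2 or 3 (adjusted p = 0.102 and 0.06) and without shared members (adjusted p = 0.0707), and none fell without old replicate 3. Of 27 glycolysis genes, Pfkfb3 (2.17-fold) and Ldha rose, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.038, adjusted p = 0.176 with an estimated correlation). The glycolysis call was lost without young replicate 1, young replicate 3 or old replicate 3 (adjusted p = 0.093, 0.0517 and 0.0752), with library size alone (0.0745), with stricter filters (0.0514 at 1 CPM and 0.0828 at a mean of 10 CPM) and with thinned counts (0.0639), and 1 gene rose without any 1 library other than young replicate 3. Of 42 autophagy and lysosome genes, Gabarapl1, Cd63 and Lamp2 rose, and 6 rose when adjusted over the list alone (camera adjusted p = 0.00817, adjusted p = 0.349 with an estimated correlation and adjusted p = 0.0599 without young replicate 3), and 1 rose without young replicate 2 or 3 and none without any 1 of the old libraries.

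Of 55 epigenetic regulators, the DNA methyltransferase gene Dnmt1, Tet1 and Satb1 fell, also when adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.281 with an estimated correlation and adjusted p = 0.0626 without old replicate 3, where 1 fell). Of 35 adhesion, niche retention and polarity genes 4 rose, with Alcam, Jam2 and Itga6 among them, and Vcam1 fell, with the same counts adjusted over the list alone and no call (camera adjusted p = 0.0697, but 0.0185 and 0.0422 without old replicates 1 and 3, 0.0422 without a filter and 0.0204 at a mean of at least 10 CPM). Of 24 imprinted genes, the non-canonical Notch ligand gene Dlk1 (9.66-fold), Impact and Zrsr1 rose, also when adjusted over the list alone, with a median log2 fold change of −0.04, a mean of 0.25 and no call with camera (adjusted p = 0.15) but a call with fry (adjusted p = 0.0215). Without old replicate 1 a single imprinted gene rose, and without old replicate 3 none did. Of 41 ribosome biogenesis genes Mycn rose and Bysl fell, also when adjusted over the list alone (camera adjusted p = 0.0927, but 0.0415 without young replicate 2 and 0.0489 with library size alone), and no gene fell without young replicates 1 or 2 or old replicates 2 or 3, while 2 fell without young replicate 3. Atf4, Dnajb1 and Dnajb9 rose among 35 protein folding genes, also when adjusted over the list alone (camera adjusted p = 0.783), and this list had a median of −0.09 although camera gave an upward direction. Of 64 interferon genes Ifitm3 and Slfn5 rose, and 3 rose when adjusted over the list alone (camera adjusted p = 0.548), but none without young replicates 2 or 3 or old replicates 2 or 3. Of 22 class I genes of the major histocompatibility complex H2-D1 rose, also when adjusted over the list alone (camera adjusted p = 0.533), but in none of the 6 fits with 1 library left out. By edgeR none of 11 class II, 88 oxidative phosphorylation and 29 lipid and cholesterol synthesis genes passed, with 1 class II gene lower and no other call when adjusted over the list alone (camera adjusted p = 0.312, 0.696 and 0.526).

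Immediate early genes had a median log2 fold change of 2.03, and with the trend against GC content and gene length removed the median was 1.97, which argues against such a bias as the whole cause. These genes can be induced while tissue is dissociated and sorted, so a difference in handling of the cells that changed along the library numbers may have contributed. Young replicate 3 has the number nearest to those of the old libraries. Over the list it lay −12.3% of the way from the other young libraries to the old mean, but 1 library cannot settle the question. Over all tested genes, the correlation with each old library rose from young replicate 1 to 2 to 3, the order of their numbers. With old replicate 1 it was 0.9444, 0.9517 and 0.9603. Total counts of the young libraries rose in that order too, and the cause was not tested. Handling that differed between the age groups and age itself cannot be told apart in this design, since no old library was numbered among the young ones. Age stays open and was not tested separately.

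Macrophage markers had a median log2 fold change of −1.74, and with every library thinned to the lowest total the median was −1.39, which argues against sequencing depth. Over members with a mean under 10 CPM, the median of the 45 markers of 8 other lists of cell types was −0.10 and that of 16 macrophage markers −2.71 (two-sided permutation p = 8e-05 across genes, which are not independent replicates). The macrophage list was examined after it had shown the lowest median, so a gap from other lists was partly built in. The limit of 10 CPM also left out the neutrophil markers S100a9 and S100a8, with log2 values of −4.14 and −3.88. Erythroid markers, not in those lists, and neutrophil markers, within them, were lower as well (6 of 23 and 3 of 8). The comparison shows only that the 45 markers did not share the macrophage fall. It cannot decide on a lower share of stem cells in the young sorts, which stays open. Macrophage RNA in the young libraries stays open, and the count of 11 of 20 members that were higher in each young library than in every old one restates the fall and decides nothing, while 4 of the 20 also stand in other lists. A change of these transcripts within HSCs and carried-over macrophage RNA cannot be told apart from these counts, and age stays open and untested.

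Substrain genes differed between the age groups, with 4 of 5 autosomal members past the threshold, and with the trend against GC content and gene length removed 4 passed, which argues against GC content or gene length bias. A substrain difference between the age groups is a candidate explanation, but the count of 4 restates the pattern and gives it no support of its own. It cannot be told apart from age here, because the labels give no substrain per mouse and any such difference would run along with age in all 6 libraries. Age stays open and untested for these genes, and reads that settle the Nnt deletion were not analysed here. A substrain difference that ran along with age would bear on every tested gene. The other differences between old and young mice therefore carry the same limit.

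In the splits of the 6 libraries into 3 and 3, the real split was the only 1 of 10 to reach 570 changed genes, with 1 the highest of the other splits, 350 higher genes, with 1 the highest other, and 220 lower genes, with 0 the highest other. It was also the only one to reach 21 gene lists, with 15 the highest other. Every other split called lists too, at least 5, while calling at most 1 gene. Camera at the preset correlation thus also called lists for groupings that mixed the ages, which limits what the 21 list calls show. The 10 splits are too few for a share under 0.05.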
